A study of Nicotiana tabacum with 9 samples.

How the data were processed

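DAP-seq was carried out on 9 samples, 3 each for HALO-tagged AmMIXTA, NtZFP8 and nuclear-targeted GFP. Per the labels' protocols, DNA of leaf primordia from separate wild-type plants was sonicated for 20 min and ligated to adaptors. The proteins were made in wheat germ extract in 3 separate expressions and bound to 20 µl of beads. They were then kept with 1000 ng of DNA for 1 h at 25 °C, and bound DNA was eluted at 98 °C. Each protein replicate met 1 DNA replicate.

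Per the series' design text, reads were filtered and mapped to the Nicotiana tabacum genome of Sierro and colleagues with 98% of reads mapped on average. Hits were found against the GFP control with a peak shape score above 2 and a p-value under 0.05. The aligner, the peak caller, their versions and the way replicates were combined are not given in the sources used here. Each deposited list holds 1 row per peak of a protein with its sequence, region, centre and length, and no column per replicate. The peak shape score is the authors' value per peak and has no unit. The p-value deposited beside a score was checked against the one-sided normal tail of that score. The largest difference was 4.3e-16 in the AmMIXTA list and 0.00543 in the NtZFP8 list, whose values are rounded. The full lists reach down to a score of about 1.64, where that tail is 0.05, so they were already filtered on p and the score criterion decides which peaks pass. NtZFP8 scores are written to 2 decimals, and 140 of its peaks stand at exactly 2.00 and were not counted as past the criterion. Depth per sample is unknown, so intervals over peaks cover counting error only, and neighbouring peaks are not independent.

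Coordinates are given as in the deposited lists, on sequences named as in the NCBI scaffold set of that genome. Regions that ran past the start of a sequence (2326 for AmMIXTA, 305 for NtZFP8) were taken from position 1, and those that wrapped around its end (314 and 220) were kept to their first part. Peaks on the plastid and mitochondrial sequences were counted apart. Genes, their descriptions and their peaks came from the authors' deposited gene tables, of 1874 and 1235 lines, whose assignment rule is not given in the sources used here. In the NtZFP8 table, 160 blank descriptions were filled from other lines of the same gene where there were any. Lines at a score of 2 or less (548 and 300) were left out of the main counts.

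The tests of shared peaks, shared genes and gene lists were fixed before the data were examined, while those of organelle peaks, sequence ends, the separate list and gene groups among shared genes were chosen afterwards. Peaks were shared where they overlapped by at least 1 bp. The overlap was tested against 1000 placements (seed 1) of the same peaks on the same sequences, whose lengths were taken as the furthest peak end seen. These lengths are lower bounds, which raises the random overlap. Shared genes were tested with Fisher's exact test (two-sided). The genes of either table (1884) served as background, because no annotation of the authors' build was used here. Of these genes, 1485 (78.8%) have an identifier in the gene table of another assembly, ASM71507v2, which was used for an added background only. Because genes came from the authors' tables, the planned upstream windows of 1000, 2000 and 5000 bp and the classes of peak position were not analysed here. Motifs and 6-base words were not analysed either, for want of a genome of the build, nor were read counts per replicate, since the lists hold none. The groups were therefore never compared over replicates.

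The 25 gene lists were patterns in gene descriptions, tested by Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over the lists. The test of AmMIXTA against NtZFP8 used genes of 1 protein only and left shared genes out of both sides. Some patterns matched by accident, such as the word formin in UDP-forming and the ending mate in glutamate. Others missed members with other names, such as RAX3-like among the MYB genes. The counts without accidental matches, and those with such members added to the MYB, cuticle, terpenoid, auxin and gibberellin lists, are alternatives chosen after seeing the data. The search for missed members was not exhaustive. All members past the criteria of the acyltransferase list (4 for AmMIXTA, 3 for NtZFP8) were of this kind. The lists for cytochrome P450s (5 and 2), receptor kinases and disease resistance (16 and 10), ribosomal proteins (12 and 7), photosynthesis (7 and 6) and transposable elements with organelle-derived genes (16 and 16) gave the counts in brackets.

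Named genes followed a fixed rule. It took the 10 described genes with the highest peak per protein, up to 10 described shared genes by the lower of their 2 scores, and the genes marked by the authors. It also took up to 4 genes with the highest score per list, to be printed for the regulator, cuticle, terpenoid, cell wall, cell cycle and hormone lists. Genes of other lists were ranked in the same way but printed after their values were seen, unless another part of the rule took them. Wilson intervals are at 95%. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

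The overlap test was tested on simulated data with 14681 peaks at random on sequences of at least 10 kb. It recovered 100% of 1000 planted overlaps, and gave a permutation p of 0.0099 with them (100 placements) and of 0.525 without. The planted peaks were slightly shifted copies of simulated ones, so their recovery was fixed in advance. Shorter sequences and clustered peaks were not simulated. The list test, over 1884 simulated genes, found a planted list of 60 genes in 20 of 20 runs and called 0 of 500 lists with nothing planted. The largest of the fixed lists, cell wall remodelling, had only 29 genes in either table. Recovery of the planted list therefore does not show that the test could find lists of the real sizes. The alternatives were stricter scores and p-values, merging of near peaks, other rules of overlap, other sets of sequences and other gene backgrounds.

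A separate list of 618 regions, with a shorter sheet of 208, is repeated byte for byte in the workbooks of both proteins. No label names its protein, and none of its regions is identical to a region of the AmMIXTA or NtZFP8 list. It was not used to count shared peaks or genes or to test shared genes. In the test of shared peaks it entered only through its region ends, which helped set the sequence lengths. Its overlap with the peaks and genes of both proteins was counted, and it served in a test of explanations for their overlap.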

Results

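DNA affinity purification sequencing (DAP-seq) was used to find where AmMIXTA and NtZFP8 bind tobacco DNA. In this assay a tagged transcription factor made in a cell-free extract is fixed on beads, sheared genomic DNA is passed over it, and the DNA that stays bound is sequenced. AmMIXTA is an R2R3-MYB factor of snapdragon known for its part in shaping epidermal cells, and NtZFP8 is a tobacco C2H2 zinc finger protein. The series set out to find the genes bound by these factors at the start of glandular trichome formation. The 9 samples fell into 3 groups of 3 replicates, AmMIXTA, NtZFP8 and a nuclear-targeted GFP that served as the negative control. All used DNA of leaf primordia of Nicotiana tabacum Petit Havana SR1. The values used here are 1 list of peaks per protein, each called by the authors against GFP, and 1 table per protein that ties part of these peaks to genes. Each score and p-value is the authors' own value for a peak, with no value per replicate, so no spread between replicates can be given for any of them. The read depth behind the peaks is unknown. A score ranks peaks within a list, and scores of the 2 proteins are set side by side without a test.

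AmMIXTA gave 29197 peaks, of which 20519 (70.3%) passed the authors' criteria of a peak shape score above 2 and a p-value under 0.05. The highest AmMIXTA peak assigned to a described gene lay at the gene for the small GTPase RABB1c-like (LOC107813663, NW_015806601.1, 103928 to 104319), with a score of 25.9. It was followed by the DnaJ protein GRV2-like (LOC107782199, 24.7), ylmG homolog protein 1-2 (LOC107774705, 21.8), a 26S protease regulatory subunit 6A (LOC107803920, 21.3) and calcineurin B-like protein 3 (LOC107819027, 21.2). F-box/kelch-repeat protein SKIP11-like (LOC107815441, 20.96), the zinc finger protein JACKDAW-like (LOC107786831, 20.8), craniofacial development protein 2-like (LOC107781153, 19.9), a trehalose-phosphate synthase (LOC107799906, 19.6) and ALWAYS EARLY 3-like (LOC107784961, 19.3) completed the 10 highest. Past the criteria, the AmMIXTA peaks had a median score of 3.00 (interquartile range 2.37 to 4.40) and a median width of 385 bp (331 to 440), and lay on 15241 sequences of the assembly. A total of 1195 genes had such a peak in the authors' gene table, and 883 of them carried a description other than uncharacterized.

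NtZFP8 gave 20957 peaks, of which 15209 (72.6%) passed the same criteria. The highest peak assigned to a described gene was again at RABB1c-like (104038 to 104353, score 20.6). Purine permease 3-like (LOC107788140, NW_015915494.1, 25037 to 25333) followed with 20.2 and SKIP11-like with 20.0. The others among the 10 highest were a G patch and ankyrin repeat protein (LOC107799652, 16.7), a pentatricopeptide repeat protein (LOC107814362, 16.5), YLS3-like (LOC107777080, 16.1), a subunit of the cytochrome b-c1 complex (LOC107816074, 16.1), ylmG homolog protein 1-2 (15.9), a chloroplastic-like ATP synthase epsilon chain (LOC107816505, 15.9) and calcineurin B-like protein 3 (15.6). The NtZFP8 peaks past the criteria had a median score of 3.09 (2.40 to 4.60) and a median width of 286 bp (259 to 305), on 10347 sequences. They were assigned to 754 genes, 548 of them described. The gene tables named 1806 of the listed AmMIXTA peaks (6.19%) and 1195 of the listed NtZFP8 peaks (5.70%), so most peaks were assigned to no gene there.

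The peaks of the 2 proteins were compared to ask whether they bind the same regions. RABB1c-like, ylmG homolog protein 1-2, calcineurin B-like protein 3 and SKIP11-like were among the 10 highest of both proteins, and each gene in either set of 10 was past the criteria for the other protein too. At RABB1c-like the peaks of the 2 proteins overlapped by 282 bp and their centres lay 10 bp apart. At kinesin-13A-like (LOC107815762), a microtubule motor, the scores were 16.1 for AmMIXTA and 15.5 for NtZFP8, and the centres lay 8 bp apart. Not all genes of the 10 highest were alike in this. The highest peaks of the proteins did not overlap at the 26S protease subunit gene (centres 613 bp apart) or at JACKDAW-like (478 bp). Nor did they at the pentatricopeptide repeat gene (642 bp) or the cytochrome b-c1 gene (652 bp). Of the AmMIXTA peaks, 10057 (49.0%, 95% Wilson interval 48.3 to 49.7) overlapped an NtZFP8 peak by at least 1 bp, and 10081 NtZFP8 peaks (66.3%, 65.5 to 67.0) overlapped an AmMIXTA peak. Random placement of the AmMIXTA peaks on their own sequences gave 2863 ± 31.7 overlaps (SD over 1000 placements, highest 2954), a ratio of 3.51 (one-sided permutation p = 0.001, the smallest the placements can give). The same test from the NtZFP8 side gave 3060 ± 34.2 and a ratio of 3.29 (one-sided permutation p = 0.001). Centres of shared peaks lay a median of 16 bp apart (8 to 29), and 87.8% were within 50 bp. The ratio was 5.54 with an overlap of at least 50% of each peak, and 13.7 on sequences of 10 kb or more, an alternative chosen after seeing the data. Both lists were called against the same GFP libraries, so part of this excess may come from the shared controls.

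The share of shared peaks rose with the score. Of the AmMIXTA peaks with a score between 2 and 3, 28.3% (27.4 to 29.2) lay on an NtZFP8 peak, against 58.5% (57.3 to 59.8) between 3 and 5, 84.0% (82.6 to 85.2) between 5 and 10, and 97.9% (96.8 to 98.7) above 10. For NtZFP8 the shares were 50.2% (49.1 to 51.3), 75.4% (74.1 to 76.6), 86.6% (85.2 to 87.9) and 95.4% (93.9 to 96.6). Partners had to pass the criteria as well. Scores of shared peaks were correlated (Pearson r = 0.78), so part of the rise may come from partners just under the cut. With partners at any listed score, 57.4% of all AmMIXTA peaks past the criteria and 73.8% of all such NtZFP8 peaks were shared. Random overlap was not computed per range of scores. Among the 917 AmMIXTA peaks above 10, 19 overlapped no NtZFP8 peak past the criteria, and 4 of these had the centre of one within 1000 bp. Among the 878 NtZFP8 peaks above 10, 40 overlapped none of AmMIXTA, and 34 of these had the centre of an AmMIXTA peak within 1000 bp.

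**Figure D1:**
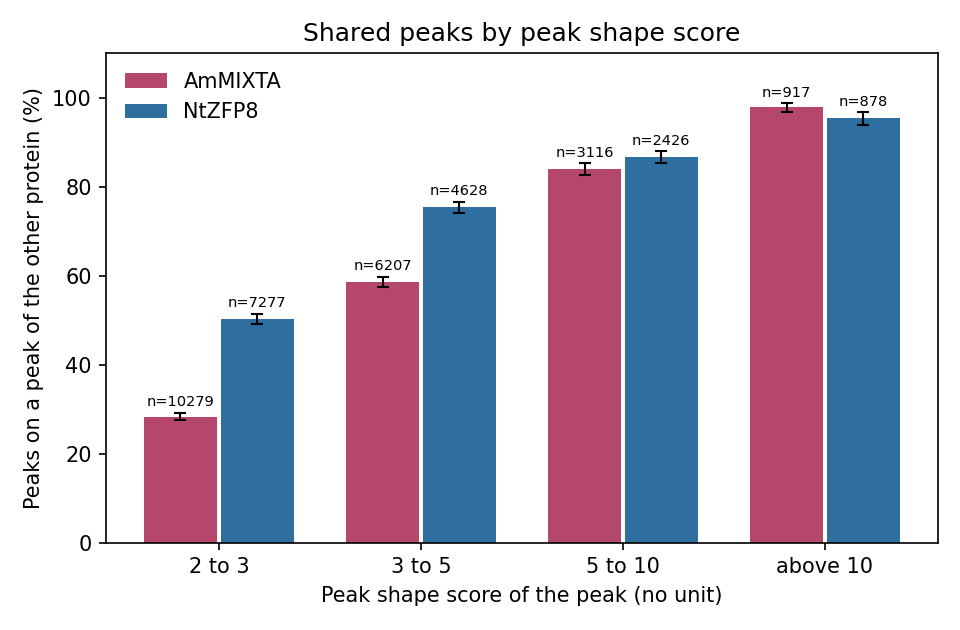
Share of peaks past the criteria (%) that overlap a peak of the other protein, by peak shape score, for AmMIXTA and NtZFP8. Bars are shares, error bars are 95% Wilson intervals and n is the number of peaks; the share goes from 28.3% to 97.9% for AmMIXTA and from 50.2% to 95.4% for NtZFP8.

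Genes were compared in the same way. Of the genes past the criteria, 592 were shared, 49.5% of the AmMIXTA genes and 78.5% of the NtZFP8 genes, and at 571 of them (96.5%) peaks of the 2 proteins overlapped. After RABB1c-like and SKIP11-like, the described shared genes with the highest scores in both tables were purine permease 3-like (19.2 for AmMIXTA, 20.2 for NtZFP8), the pentatricopeptide repeat protein (16.6 and 16.5), YLS3-like (16.3 and 16.1), ylmG homolog protein 1-2, calcineurin B-like protein 3, la-related protein 1A-like (LOC107770309, 17.2 and 15.6), kinesin-13A-like and the G patch protein (15.4 and 16.7). The highest peaks of the 2 proteins did not overlap at la-related protein 1A-like, where their centres lay 882 bp apart, or at the pentatricopeptide repeat gene, where they lay 642 bp apart. Shared genes without a description, chosen after their values were seen, ranked among these, such as LOC107779393 (16.6 and 17.8), LOC107803124 (18.6 and 16.3) and LOC107782682 (20.7 and 16.1). Over the 1884 genes in either table the odds ratio of being bound by both was 3.19 (Fisher's exact test, two-sided, p = 1.76e-29). This background holds only genes with a peak and so lowers the ratio. Against the protein-coding genes of another tobacco assembly, where 429 shared genes were found and 8.19 were expected of independent lists, it was 454, and with a score above 3 over the 1884 genes it was 19.4. The background of the other assembly counts every gene as able to enter both tables. The tables assigned few peaks to genes, by a rule that is not given. Any limit common to both tables would raise the 454, so it is no measure of shared binding alone. Among the 1884, the genes bound by neither were those listed only at a score of 2 or less. The ratio of 3.19 and its p-value thus depend on how many such genes were deposited. With a score above 3 this class grew, so 19.4 cannot be set against 3.19. The test also counts genes as independent, though 66 AmMIXTA and 39 NtZFP8 peaks of the tables were each assigned to more than 1 gene.

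A further 603 genes were past the criteria for AmMIXTA alone and 162 for NtZFP8 alone. Of these, 71 and 61 stood in the table of the other protein at a score of 2 or less. The highest described genes missing from the NtZFP8 table, chosen after their values were seen, were replication protein A 70 kDa subunit A-like (LOC107807453, 17.6), a phosphoribosylamine-glycine ligase (LOC107830634, 13.1), the transcription factor bHLH10-like (LOC107791312, 9.28), a vacuolar sorting protein (LOC107821090, 8.80) and the MADS-box protein AGL42-like (LOC107763429, 7.90). Peaks at the first pair nevertheless lay on NtZFP8 peaks of the full list, which the NtZFP8 gene table does not assign to these genes. No NtZFP8 peak at any listed score overlapped the peaks at bHLH10-like, the vacuolar sorting protein or AGL42-like. In the other direction, beta-amylase 3 (LOC107826071, 8.68) and an ABA-inducible protein (LOC107773639, 5.17) were missing from the AmMIXTA table but lay on AmMIXTA peaks past the criteria. The peaks at a tropomyosin-like gene (LOC107823291, 4.29), an inositol polyphosphate 5-phosphatase (LOC107803457, 4.09) and MLO-like protein 1 (LOC107761998, 3.66) overlapped no AmMIXTA peak. Over all genes found for 1 protein, 5 of the 603 and 5 of the 162 had a peak on a peak of the other protein past the criteria. At any listed score these counts were 64 (10.6%, 8.40 to 13.3) and 57 (35.2%, 28.3 to 42.8).

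Gene groups were counted by words fixed for their descriptions, so genes described in other words are not in the counts. The list for regulators of trichomes and of the epidermis held 6 AmMIXTA genes and 4 NtZFP8 genes, all 4 of which were shared. GLABRA 2-like (LOC107819990), a homeodomain-leucine zipper gene of a type that controls trichome outgrowth, had a peak at 46962 to 47351 of NW_015823889.1 for AmMIXTA (score 9.19) and at 47039 to 47350 for NtZFP8 (7.72). The centres lay 38 bp apart. Most other members were trichome birefringence-like genes, which are named for a trichome mutant, from a family that acts in acetylation of cell wall polysaccharides. Of these, trichome birefringence-like 39 (LOC107797195) had 5 peaks for each protein between 15517 and 18178 of NW_015927842.1, with highest scores of 7.88 and 9.22. Trichome birefringence-like 19 (LOC107823824) had scores of 7.35 and 8.16, birefringence-like 33 (LOC107816582) had 3.02 and 3.04, and birefringence-like 25 (LOC107764985) had 4.37 for AmMIXTA only. Without the birefringence genes the list held 2 AmMIXTA genes and 1 NtZFP8 gene. The second AmMIXTA gene, named after its value was seen, was protodermal factor 1-like (LOC107795275, 2.31), an epidermal marker.

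Among transcription factor families, genes described as MYB numbered 5 for AmMIXTA and 1 for NtZFP8. The one of these found for both, MYB6-like (LOC107803458), had a score of 18.1 for AmMIXTA (36809 to 37219 of NW_015937367.1) and 12.35 for NtZFP8 (37207 to 37500), and these peaks overlapped by only 13 bp. The other AmMIXTA members, among them MYB3-like (3.02), Myb-related 308-like (2.98) and a second MYB6-like gene (LOC107793397, 2.94), were absent from the NtZFP8 table. A pair of RAX3-like genes, also of the R2R3-MYB family but not described as MYB and chosen after their values were seen, were shared (LOC107779404, 3.84 and 4.45, and LOC107789774, 4.2 and 3.2), which makes 7 and 3. Zinc finger genes numbered 9 and 6, with 5 shared. JACKDAW-like, which belongs to a C2H2 family of root patterning factors, had 1 AmMIXTA peak (33950 to 34344 of NW_015913826.1, score 20.8) and 2 NtZFP8 peaks, 1 at the same place (33997 to 34337, score 7.30) and a higher one next to it (34447 to 34740, score 11.95). CONSTANS-LIKE 10-like (LOC107816562) had scores of 6.55 and 10.1. The CCCH proteins 65-like (LOC107805435) and 62-like (LOC107806010) had 4.85 and 2.48, and 3.28 and 4.18, and MYM-type protein 1-like (LOC107784168) had 2.88 and 4.28. Basic helix-loop-helix genes numbered 4 and 3, led by the shared bHLH101-like (LOC107828347, 11.5 and 8.19), with bHLH112-like (LOC107831217) at 3.05 and 2.17. The genes bHLH10-like and bHLH30-like (LOC107832488, 3.21) were found for AmMIXTA and bHLH80-like (LOC107777531, 2.08) for NtZFP8. NAC and WRKY genes numbered 7 and 4, with NAC76-like (LOC107831613) at 4.48 and 6.02 and a pair of WRKY4 genes at 3.18 and 2.01 (LOC107784946) and at 3.06 and 2.18 (LOC107820331). WRKY33 (LOC107811911, 2.89) was found for AmMIXTA and WRKY40 (LOC107801001) had 2.94 for NtZFP8 and 1.75, under the criterion, for AmMIXTA. The AP2/ERF genes numbered 3 and 2. Of these, WIN1-like (LOC107788794), a regulator of wax and cutin, scored 2.78 for AmMIXTA and 1.79, under the criterion, for NtZFP8. ERF113-like (LOC107783671) had 2.94 and 2.03, and dehydration-responsive element-binding protein 3-like (LOC107791342) had 2.12 and 4.2. Homeodomain genes numbered 2 and 1, GLABRA 2-like and, for AmMIXTA, zinc-finger homeodomain protein 2-like (LOC107796987, 2.11).

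**Figure D2:**
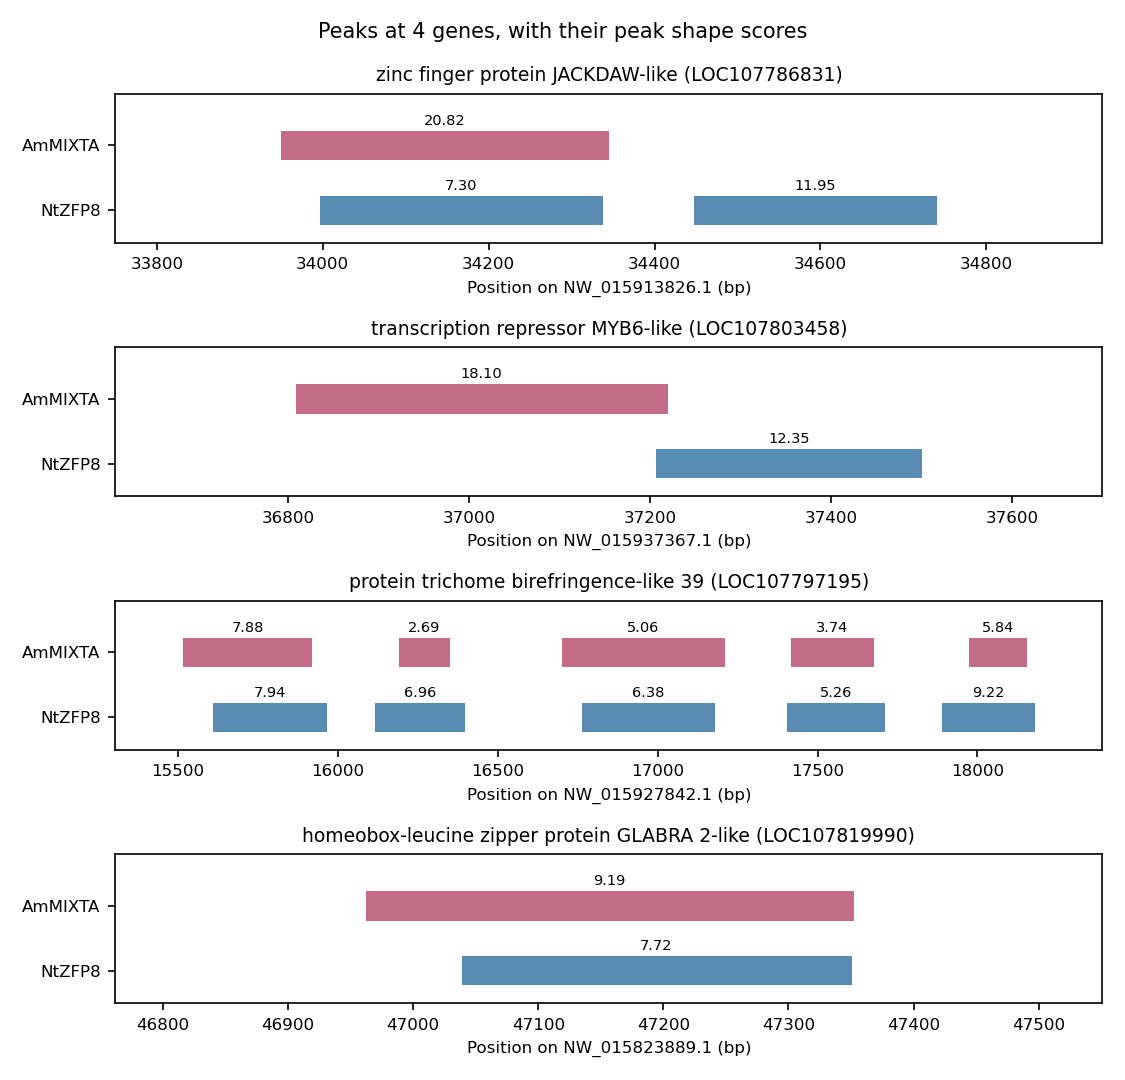
Peaks past the criteria of AmMIXTA and NtZFP8 at JACKDAW-like, MYB6-like, trichome birefringence-like 39 and GLABRA 2-like, by position on the assembly sequence (bp), with the peak shape score above each bar. The peaks of the proteins overlap at GLABRA 2-like and at all 5 places of birefringence-like 39, and at MYB6-like by 13 bp. At JACKDAW-like the AmMIXTA peak overlaps the lower NtZFP8 peak (score 7.3) and not the higher one.

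The cuticle and wax list held 7 AmMIXTA and 4 NtZFP8 genes, 3 of them shared, among them peroxisomal long chain acyl-CoA synthetase 6 (LOC107780683, 4.19 and 3.22) and the GDSL lipase At5g37690-like (LOC107817898, 3.45 and 2.53). The lipase At4g01130-like had 2.82 and 2.29 (LOC107780608), and another gene of that name had 2.45 for NtZFP8 (LOC107806517). Long chain acyl-CoA synthetase 4-like (LOC107793159) had 2.89 for AmMIXTA. Outside its words, and chosen after the values were seen, elongation of fatty acids protein 3-like (LOC107826684) was shared at 6.76 and 4.60. Members seen for AmMIXTA only and named after their values were seen included ECERIFERUM 1-like (LOC107759567, 2.30), of wax synthesis, and fatty acyl-CoA reductase 2-like (LOC107765773, 2.25). Lipid transfer proteins numbered 5 and 1, or 4 and 1 without accidental matches, and non-specific lipid-transfer protein 1 (LOC107812329) had 6.45 and 6.75. A non-specific lipid-transfer protein 1-like gene (LOC107823858) had 2.64 for AmMIXTA and 1.71, under the criterion, for NtZFP8. The AmMIXTA peak at glycolipid transfer protein 3-like (LOC107761970, 2.51) lay on an NtZFP8 peak past the criteria in the full list. No gene of the terpenoid list passed the criteria for either protein. The 3 members in the tables, named after their values were seen, were a pair of 5-epi-aristolochene synthases for AmMIXTA (LOC107769201 at 1.93, LOC107799408 at 1.69) and a geranyltransferase for NtZFP8 (LOC107803398 at 1.99). Outside its words, and also chosen after the values were seen, 3 genes of terpenoid metabolism passed for AmMIXTA. They were ent-kaurene oxidase (LOC107792085, 2.52), which acts in gibberellin synthesis, and a pair of carotenoid cleavage dioxygenases (LOC107817468, 2.96, and LOC107817154, 2.57). Phenylpropanoid and flavonoid genes numbered 10 and 4, all 4 shared. Anthocyanidin reductase-like (LOC107792951) had 5.62 and 7.77, while phenylalanine ammonia-lyase-like (LOC107802063), at 4.22 for AmMIXTA, was absent from the NtZFP8 table.

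The cell wall list held 21 AmMIXTA and 12 NtZFP8 genes, 10 of them shared. A polygalacturonase-like gene (LOC107779415) had 10.3 and 5.41, and lysine-rich arabinogalactan protein 18-like (LOC107779301) had 7.72 and 8.19. Callose-binding protein 3-like (LOC107772798) had 4.40 and 2.72, pectinesterase PPE8B-like (LOC107792167) 2.78 and 4.32, and polygalacturonase At1g48100-like (LOC107802133) 2.50 and 3.41, while an extensin gene (LOC107832782) had 4.86 for AmMIXTA only. Cytoskeletal genes numbered 13 and 12, or 8 and 8 once genes matched by accident were left out. Among them were kinesin-13A-like, tubulin-folding cofactor D-like (LOC107787597, 17.4 and 11.0) and formin-like protein 14 (LOC107824924, 4.81 and 7.80). Of the 4 AmMIXTA and 1 NtZFP8 cell cycle genes, the spindle checkpoint gene BUBR1-like (LOC107799694) was shared at 7.84 and 7.10, and cell division cycle 20.2-like (LOC107779511, 4.19), cyclin C13-1-like (LOC107812029, 3.70) and cyclin-D7-1 (LOC107800608, 2.63) were found for AmMIXTA. The peak at cell division cycle 20.2-like lay on an NtZFP8 peak past the criteria in the full list. Export transporters numbered 11 and 6, or 6 and 5 without accidental matches, led by ABCG23-like (LOC107771139, 14.1 and 11.55).

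The gibberellin list held 3 AmMIXTA and 2 NtZFP8 genes, with the gibberellin-inactivating gibberellin 2-beta-dioxygenase 2-like (LOC107770071) at 6.52 and 2.47 and 2-beta-dioxygenase 8-like (LOC107792401) at 3.09 and 4.46. Gibberellin-regulated protein 9-like (LOC107810245) had 2.56 for AmMIXTA. The jasmonate list held 4 and 4, among them the receptor gene coronatine-insensitive 1-like (LOC107819687, 2.68 and 4.38) and jasmonate O-methyltransferase (LOC107813811, 3.43 and 3.75). TIFY 6B-like (LOC107807057) had 3.02 and 2.88, from highest peaks that did not overlap. A 12-oxophytodienoate reductase-like gene (LOC107817070) had 3.82 for NtZFP8 and 1.85, under the criterion, for AmMIXTA, and a lipoxygenase homology domain gene (LOC107782824) had 2.06 for AmMIXTA. Cytokinin dehydrogenase 3-like (LOC107799019), of 2 genes for each protein, had 5.16 and 4.44, beside ARR12-like (LOC107769400, 2.30) for AmMIXTA and LOG8-like (LOC107784101), which had 3.07 for NtZFP8 and 1.72, under the criterion, for AmMIXTA. The auxin list held 2 and 1, with ARG7-like (LOC107779885) at 2.89 and 2.49 and IAA32-like (LOC107764089) at 2.81 for AmMIXTA. Hormone genes outside the words of these lists, chosen after their values were seen, were tryptophan aminotransferase-related protein 2-like (LOC107767293, 10.97 and 7.44), of a family that holds auxin synthesis enzymes, and ABSCISIC ACID-INSENSITIVE 5-like protein 2 (LOC107815582, 3.10 and 2.98).

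No list differed by Fisher's exact test (two-sided, Benjamini-Hochberg over 25 lists) from the other genes of the tables. By this exact test the count at an adjusted p under 0.05 was 0 of 25 for AmMIXTA (lowest adjusted p = 1), 0 of 25 for NtZFP8 (lowest 0.545) and 0 of 25 for genes of AmMIXTA alone against genes of NtZFP8 alone (lowest 1). At an unadjusted p under 0.05 the counts were 1, 1 and 0. The unadjusted calls of the exact test were terpenoid metabolism for AmMIXTA, with none of its 3 members past the criteria (p = 0.0488), and the transposable element and organelle-derived genes for NtZFP8, 16 genes with an odds ratio of 2.70 (p = 0.0218). With the genes of other names added, the exact test of the terpenoid list gave p = 0.267 for AmMIXTA and p = 0.0464 (adjusted 0.490) for NtZFP8, with 0 of 7 genes past the criteria for NtZFP8. The lists are short and their background holds only genes with a peak, so these tests do not show that the groups were bound alike.

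**Figure D3:**
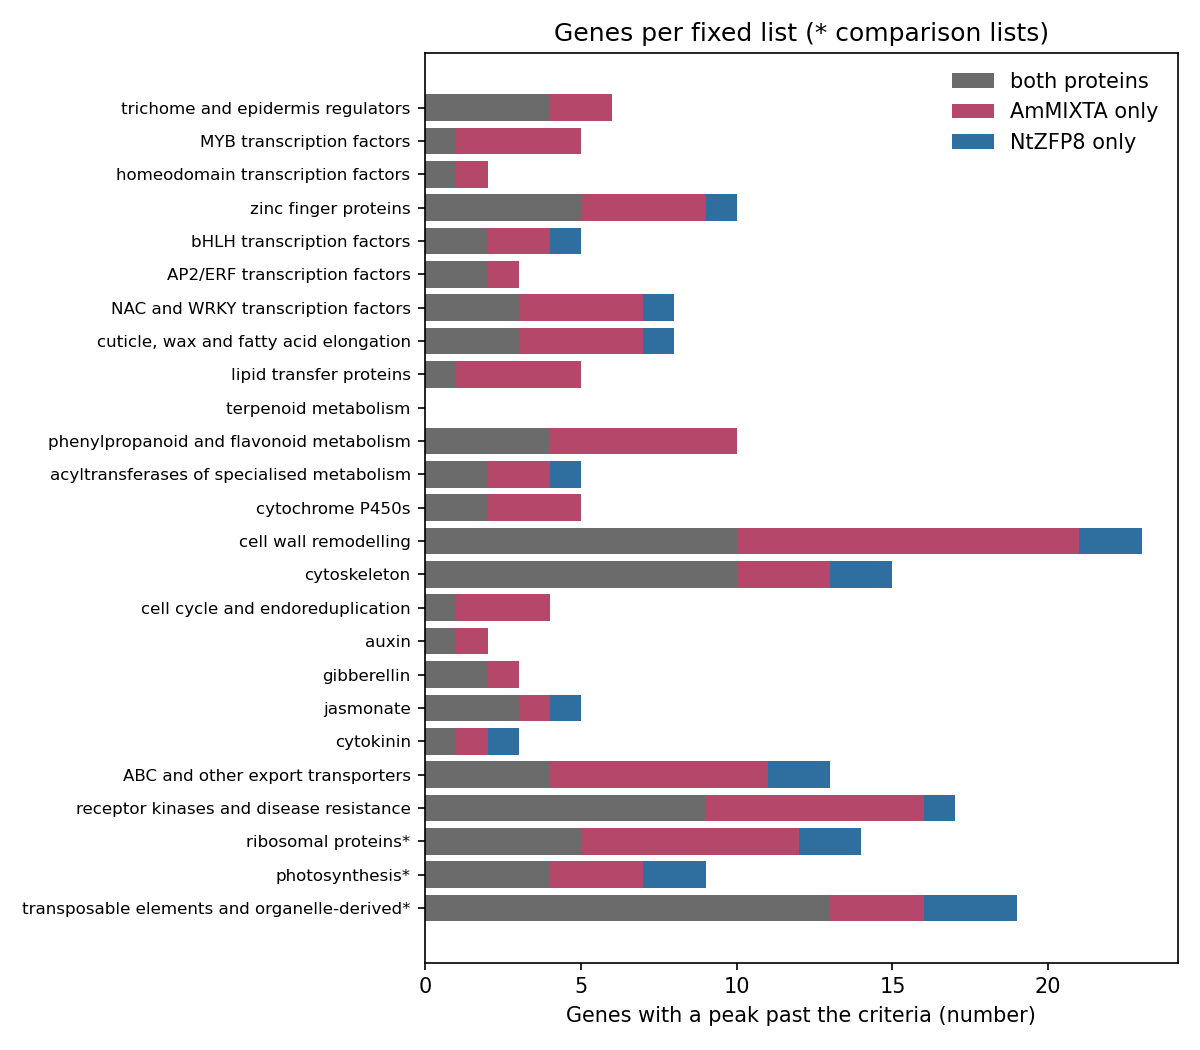
Number of genes past the criteria in each of the 25 fixed lists, split into genes of both proteins, of AmMIXTA only and of NtZFP8 only. Cell wall remodelling has 10 shared genes and the terpenoid list has none past the criteria.

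In the NtZFP8 gene table the authors had marked 10 peaks at 9 genes by hand. Of these genes, 7 were past the criteria for NtZFP8, and the same 7 were past them for AmMIXTA. They were ABCG23-like, JACKDAW-like, GLABRA 2-like, AGL66 (LOC107765071, 5.29 for AmMIXTA and 4.54 for NtZFP8), NLP7-like (LOC107766341, 3.16 and 4.14), SOC1-like (LOC107828738, 3.30 and 3.96) and long chain acyl-CoA synthetase 6. The mark beside GLABRA 2-like names a tomato homologue. The other marked genes, the MADS-box gene AGL27 (LOC107764452, 1.83) and an undescribed gene marked as an ABCG transporter (LOC107793099, 1.92), were under the criterion for NtZFP8 and absent from the AmMIXTA table.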

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

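The tests of organelle peaks, sequence ends and the third list below were all chosen after the data were seen, and their p-values count peaks, which are not replicates. NtZFP8 had 117 plastid peaks past the criteria and AmMIXTA 0 of 20519, which allows a share of up to 0.0146% if 3 peaks are taken as the limit of a count of 0. On the mitochondrial sequence AmMIXTA had 7 and NtZFP8 had 79 (odds ratio 0.0654, Fisher's exact test, two-sided, adjusted p = 5.33e-22 over 4 tests). With stricter scores the mitochondrial counts were 3 and 27 above 3, and 1 and 4 above 5, and the difference was not tested at these scores. The plastid counts were 0 and 77 above 3, and 0 and 23 above 5. Both organelles together gave 7 against 196, an odds ratio of 0.0261 (exact test, adjusted p = 1.08e-62). Peaks that ran past a sequence end, at its start or its finish, made up 9.14% of the AmMIXTA peaks (1876) and 2.27% of the NtZFP8 peaks (346), an odds ratio of 4.32 (exact test, adjusted p = 1.1e-173). Over all listed peaks the difference lay mostly at starts (2326 for AmMIXTA, 305 for NtZFP8) rather than finishes (314 and 220). How the peaks were called is not known, so a difference in calling cannot be told apart from one between the proteins. The AmMIXTA peaks were also wider, with medians of 385 and 286 bp. These differences were seen in 1 list per protein and were not tested over replicates.

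The third list, for which no label names a protein, held 618 regions in the authors' deposited table, with scores up to 10.5. Of these, 45 lay on the plastid and 56 on the mitochondrial sequence. Of its 517 nuclear regions, 452 (87.4%, 84.3 to 90.0) lay on a listed AmMIXTA peak, 487 (94.2%, 91.8 to 95.9) on a listed NtZFP8 peak, 438 on both and 16 on neither. Its shorter sheet named 178 genes, of which 52 were in the AmMIXTA gene table and 52 in the NtZFP8 gene table.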

How the results depend on the processing

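No paired analysis was possible because the lists hold 1 value per peak and protein and none per replicate, so leaving out a replicate, a replicate block and a split of the GFP controls were not run either. Alternatives that need an annotation, a genome or read counts (upstream windows, peak positions, motifs, count models) were not run, and depth is unknown. Among the rest, those on sequence length, all deposited peaks, nuclear sequences, accidental matches, members with other names, organelle counts, scores of exactly 2.00, the other-assembly background and all table genes were chosen after seeing the data. Peak counts fell with stricter criteria, by construction: AmMIXTA to 10240 above a score of 3, 4033 above 5 and 9719 at a p-value below 0.001, and NtZFP8 to 7932, 3304 and 7589. Shared genes fell to 364 above 3. They were 752 without a score criterion. Merging peaks within 500 bp left 18964 and 13220, and counting scores of exactly 2.00 gave 15349 for NtZFP8. Adjusting the p-values within lists already limited to 0.05 is void and kept 29197 and 19934. The excess of shared peaks over random placement held under all 8 alternatives run (5 planned), at ratios from 2.77 (centres within 500 bp) to 13.7 (sequences of 10 kb or more), with AmMIXTA shares of 45.6% to 55.5% (200 placements each, or 20 for the 50% overlap and centre rules). The odds ratio of shared genes stayed above 1, at 19.4 above a score of 3 and 454 with the other background. The value of 19.4 depends on how many genes of lower score were in the background. The value of 454 counts genes that may never have been able to enter the tables, which would raise it. The count of lists past the adjusted threshold was 0 under all 3 alternatives run (0 to 2 at an unadjusted p under 0.05, Fisher's exact test). Of 54 list and organelle counts, 33 moved by over 1.5 times above a score of 3, 6 of 50 without accidental matches and 3 of 50 with members of other names.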

Other observations

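Of the tests in this part, only that of neighbouring peaks had its outcome set down before its result was seen. The random placement test had been planned, but its outcome was set down afterwards, and the tests of the third list, of sequence ends and of gene groups among shared genes were chosen after the data were seen.

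Several genes carried many peaks of both proteins. The uncharacterized gene LOC107778168 on NW_015903728.1 had 8 AmMIXTA and 15 NtZFP8 peaks past the criteria, the highest at 7.85 and 7.19. LOC107787902 had 6 and 7 peaks, LOC107792561 had 5 and 6, and LOC107795990 had 3 and 9. A cytochrome b6 gene on a scaffold other than the organelle sequences (LOC107769160) had 6 for each, with top scores of 12.6 and 11.3. Other genes of plastid type on such scaffolds, chosen after their values were seen, also had high scores for AmMIXTA and NtZFP8. Among them were a Rubisco large chain-like gene (LOC107793518, 19.0 and 12.8), a photosystem II D2-like gene (LOC107808202, 12.4 and 12.8), a photosystem I A2-like gene (LOC107796558, 10.1 and 12.5) and Ycf2-like (LOC107770945, 14.0 and 11.99). The chloroplastic-like ATP synthase epsilon chain gene (LOC107816505) also lay on such a scaffold, at 13.5 and 15.9. The plastid sequence itself gave 0 AmMIXTA peaks.

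Why the strongest peaks of the MYB factor and the zinc finger factor coincide is open. Chance placement is argued against by the ratio of 3.51 over random. Peaks that ran past a sequence end made up 8.91% of shared AmMIXTA peaks and 9.37% of the others. Shares this low and alike mean that such peaks do not account for the overlap. Peaks near an end that did not run past it were not examined. Regions pulled down whatever the protein, or low in the shared GFP libraries, cannot be told apart from binding. Within 4 score bins, shared NtZFP8 peaks lay on the third list more often (Mantel-Haenszel odds ratio 1.74, 95% interval 1.29 to 2.36). The protein of that list is unknown and may be one of these 2. The odds ratio of 1.74 is also partly fixed, as 87.4% of the list's nuclear regions lay on AmMIXTA peaks. The 21.8 (10.3 to 46.1) for AmMIXTA peaks is nearly fixed, as 94.2% of the list's nuclear regions lay on NtZFP8 peaks. Repeats or collapsed copies may contribute. Of shared AmMIXTA peaks, 24.2% had another within 1000 bp, against 14.5% of the others (odds ratio 1.62, 1.49 to 1.75, over 4 score bins). A near peak does not by itself show a repeat. Without sequences of more than 10 peaks, 47.8% of AmMIXTA peaks were shared, at a ratio of 3.50 over random. This kept 19794 of the 20519 AmMIXTA peaks, so the share could hardly move and says little about repeats. A common sequence preference, the biological explanation, was not tested.

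A preference of shared binding for some gene groups could not be shown or excluded. Over the 25 lists, shared genes against genes of 1 protein gave a lowest adjusted p of 0.882 (Fisher's exact test, two-sided). By the same exact test 1 list had an unadjusted p under 0.05, the transposable element and organelle-derived genes, with 13 shared genes and an odds ratio of 2.84 (p = 0.0353).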
